A study of Caenorhabditis elegans with 4 samples.

How the data were processed

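The series profiled where LIN-37 sits on the genome of Caenorhabditis elegans late embryos by ChIP-seq, in which formaldehyde-fixed chromatin is sheared, precipitated with an antibody and sequenced. Per the labels' protocols, embryos of the wild-type strain N2 were released from gravid adults by bleaching, incubated for 3.5 hours and frozen. Ground material was fixed in 1% formaldehyde for 10 minutes and sonicated, and LIN-37 was precipitated with an affinity-purified rabbit polyclonal antibody. Libraries were amplified for 18 cycles and gel-selected for fragments of 250 to 350 bp. The 4 samples are 2 ChIP libraries and 2 input libraries. Peak lists were analysed for both ChIP libraries. The input libraries were not analysed here as separate samples, so no background level is given beside the peaks.

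Each peak list gave a chromosome, start and end, and a score for each peak. Per the file headers, coordinates are in WormBase build WS210, and comment lines in each file record that coordinates had been carried over from another build, with 1 feature on chromosome III whose length changed in that step. Per the file headers and feature names, the deposited scores belong to peaks named for the MACS caller, while the source column names MA2C. The version of the caller, the aligner, the control used and any filter are not given in the sources used here. Deposited scores were never under 50 and piled up at exactly 3100; the files do not state their scale, so a score was used to describe, rank, split or filter peaks within a list, and its ranks were correlated between the matched peaks of the replicate lists. There is 1 list per ChIP library and 1 list for the whole series, called the combined list below. Whether the authors made the combined list from pooled reads or from merged lists is not given in the sources used here. Read depth is unknown for every library, so intervals cover only the counting of peaks.

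Peaks were taken as 1-based intervals. The 6 peaks in the combined list and the 6 in the replicate 2 list that lacked a start coordinate lie at chromosome beginnings and were taken to begin at position 1. Peaks overlapped if they shared at least 1 bp. A combined-list peak was called supported if it overlapped a peak in each replicate list. Matched peaks were mutual best overlaps between the replicate lists. The length of a chromosome was taken as the highest peak end on it in the 3 lists, since chromosome lengths of this build were not used here. The overlap of the replicates was tested against 100000 random placements of the replicate 1 peaks on their own chromosomes (one-sided permutation test, whose smallest possible p is 1e-05). Peak numbers per chromosome were tested against length with exact binomial tests (two-sided), shares were compared with Fisher's exact test (two-sided), and shares carry exact Clopper-Pearson 95% intervals. Clustering was tested with the variance to mean ratio of peak numbers in 100 kb windows against 100000 random placements. Adjusted p-values are Benjamini-Hochberg values over the 6 chromosomes or over the 5 tests of the closing section. The labels do not say that the replicates came from separate cultures, so agreement between them may be technical agreement only, and peaks are not independent replicates. The exact binomial and Fisher's exact tests count each peak as independent. Where peaks cluster, their p-values can be too small and the intervals too narrow.

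Tests of gene promoters, of divergent gene starts, of gene lists and of sequence motifs were planned and not run: no annotation or sequence of build WS210 was used here, and the gene table at hand is of another build, so no peak was assigned to a gene. For the same reason X was tested by peak number against length, which was the fallback stated in advance for a missing annotation, and autosome centres, for which no fallback had been stated, were tested by peak positions against length in place of genes. The rule for naming items fell back to its stated alternative, the 10 supported peaks with the highest score, given by coordinate. The tests of replicate overlap, support, score ranks and the share of X against length, the rule for naming peaks and the alternatives named next were fixed before the data were examined. The tests of each chromosome, of peak positions in chromosome centres and ends, of clustering, of widths and of the score of 3100 were chosen after the files had been seen. Alternatives were an overlap of 50% of both lengths, the upper 50% of peaks by score, all combined-list peaks, and support by one replicate only. The tests were tested on simulated data: with 200 planted shared peaks the replicate overlap was found in 20 of 20 simulated lists and in 1 of 20 without planted peaks. An X density at 50% of the expected one was found in 20 of 20 simulated counts and in 0 of 20 without it. These counts were drawn from the same binomial model that the test assumes. They do not show how the test behaves where peaks cluster. Clustering with 200 planted peaks was found in 16 of 20 simulated lists and in 0 of 20 without. The planted peaks took positions from peaks on any chromosome, and positions beyond a limit were all set to that limit. Many were therefore not placed next to another peak, and the whole combined list was used. This simulation does not show how well clusters of supported peaks are found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.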

Results

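LIN-37 is a subunit of the DREAM complex of C. elegans, which joins an E2F-DP heterodimer and a retinoblastoma-like protein and is known as a regulator of cell cycle and germline genes. The series asked where LIN-37 is bound in wild-type late embryos. The data are peak lists from 2 ChIP libraries and a combined list of the series; 2 input libraries make up the other group. Replicate 1 had 2166 peaks, replicate 2 had 1854 and the combined list had 1932. The lists covered 2.12 Mb, 3.13 Mb and 3.62 Mb of the genome, respectively. The median peak width was 825 bp in replicate 1, 1468 bp in replicate 2 and 1637 bp in the combined list. Read depth is unknown, and there is 1 list per library, so levels carry counting intervals and no SD.

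The first comparison asked whether the replicates found the same regions. Of the replicate 1 peaks, 1735 (80.1%, 95% interval 78.4 to 81.8) overlapped a replicate 2 peak, and 1660 of the replicate 2 peaks (89.5%, 88.1 to 90.9) overlapped a replicate 1 peak. Random placement of the replicate 1 peaks gave 124.5 ± 10.8 overlaps (mean and SD of the placements) and never more than 177. The observed number was 13.9 times the random mean (one-sided permutation test, p = 1e-05, the smallest it can give). With 50% of both lengths shared, 1374 replicate 1 peaks (63.4%) had a replicate 2 partner. Replicate 1 peaks were narrower (median 825 against 1468 bp), so this limit depends on width as well as position. Random placement draws on the whole chromosome and not on open chromatin or mappable sequence alone. Peaks without a partner scored low: the median score was 80.5 for the 431 such peaks of replicate 1 and 80.3 for the 194 of replicate 2, against 841.8 and 745.3 for the shared peaks.

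In the combined list, 1627 of 1932 peaks (84.2%, 82.5 to 85.8) were supported by both replicates. A further 154 overlapped replicate 1 only, 108 overlapped replicate 2 only, and 43 overlapped neither. Support was larger in higher classes of the score, with intervals that did not overlap. It was 21.1% (16.4 to 26.4) for the 275 peaks scoring from 50 to under 100, and 85.1% (82.0 to 87.9) for the 591 scoring from 100 to under 500. All 1066 peaks scoring 500 or more were supported, with a lower 95% limit of 99.7%. The combined list is of the same series as the replicate lists. Its scores and their support therefore do not come from separate data. The overlap required mattered: with 50% of both lengths shared, 60.7% of the combined-list peaks were supported. This limit depends on width as well as position. The median width was 825 bp in replicate 1 and 1637 bp in the combined list, so a peak wholly inside another can miss it.

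**Figure D1:**
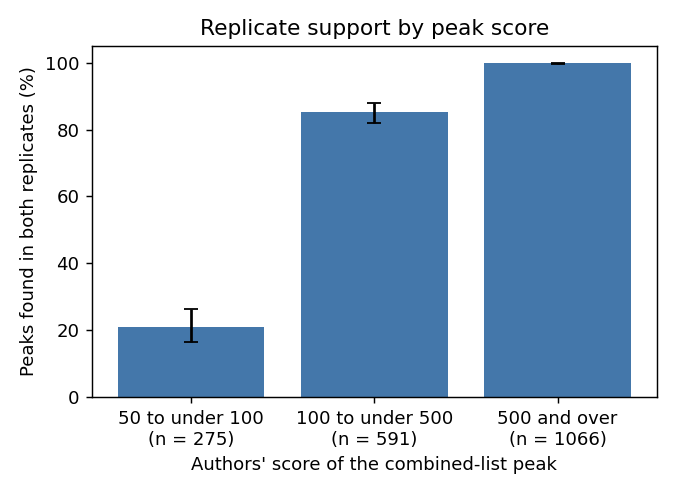
Share of combined-list peaks that overlapped a peak in both replicate lists (y axis, percent) in 3 classes of the authors' score (x axis), with exact 95% intervals. The share goes from 21.1% in the lowest class to all 1066 peaks in the highest class.

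The 1660 matched peaks lay at nearly the same place in both lists, with a median distance between peak centres of 49.5 bp. Replicate 2 peaks were the wider in 1627 of these pairs (98.0%), by a median factor of 1.57, and 1511 replicate 1 peaks (91.0%) lay wholly inside their partner. In 71 cases 1 replicate 2 peak spanned 2 or more replicate 1 peaks, which numbered 148 in all. The authors' scores ranked the matched peaks alike, with a Spearman's rho across peaks of 0.93 (bootstrap 95% interval 0.92 to 0.93). Among the 1164 pairs in which both scores were under 3100, rho was 0.84 (0.82 to 0.86). These correlations run across peaks, which are not independent replicates, and no p-value is given for them.

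**Figure D2:**
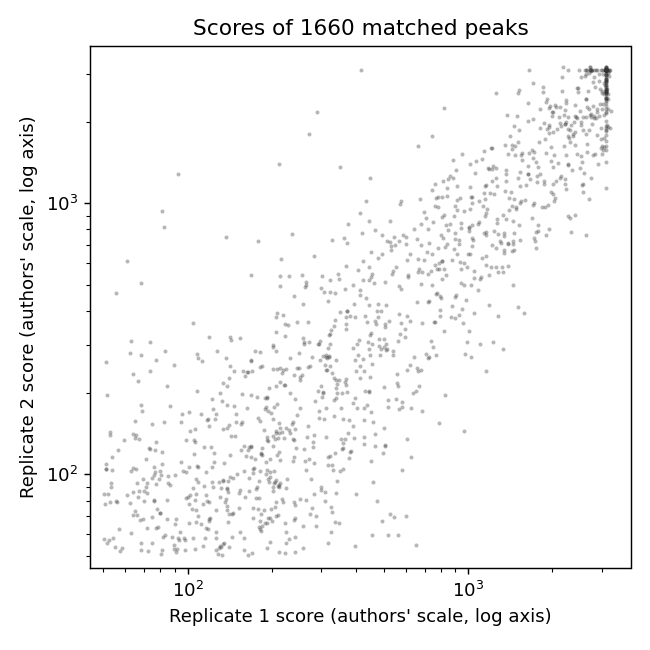
Authors' score in replicate 1 (x axis, log scale) against replicate 2 (y axis, log scale) for the 1660 matched peaks, 1 point per pair. The points follow a rising band (rho 0.93), and 393 pairs have both values at exactly 3100.

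The next comparison asked how the bound regions were spread over the chromosomes. Chromosome X held 76 of the 1627 supported peaks, or 4.29 peaks per Mb, against 18.8 per Mb on the 5 autosomes. The density on X was 0.23 times that of the autosomes (95% interval 0.18 to 0.29, exact binomial test, p = 1.41e-56). The same ratio was 0.28 (0.23 to 0.34) in the replicate 1 list and 0.25 (0.20 to 0.31) in the replicate 2 list. Among autosomes, chromosome III had the most peaks per Mb (25.6, 353 peaks), followed by I (24.2, 364 peaks), II (19.1, 292 peaks), IV (16.95, 296 peaks) and V (11.8, 246 peaks). Against its share of the total length, X included, chromosome III (adjusted p = 1.03e-17, exact binomial test), I (1.15e-14) and II (0.00359) held more peaks. In the same test V (7.61e-09) and X (8.44e-56) held fewer, and IV did not pass (0.433). The low count on X raises the share of peaks on every autosome. Beside the 18.8 per Mb of the autosomes together, II (19.1) was close and IV (16.95) was lower. No test was run among the autosomes alone. Lengths were approximated by the highest peak end.

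**Figure D3:**
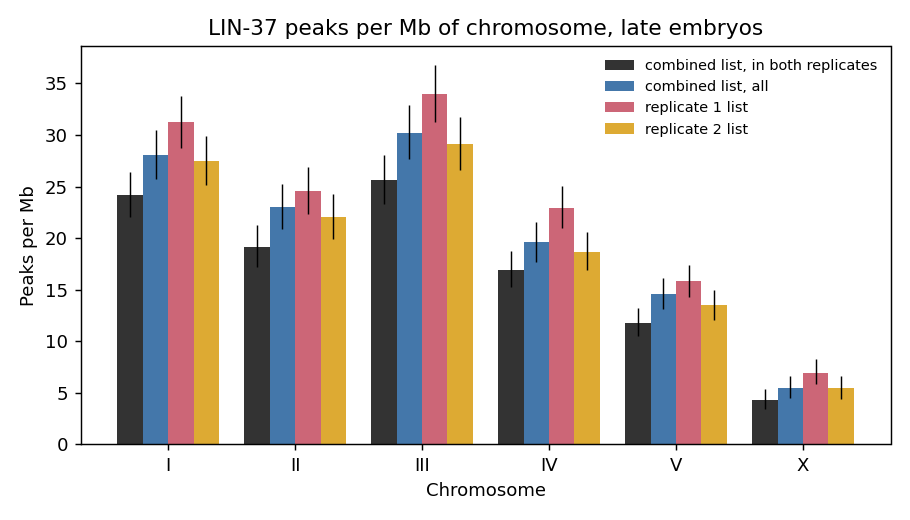
Peaks per Mb (y axis) on each chromosome (x axis) for the supported combined-list peaks, all combined-list peaks and each replicate list; error bars are exact 95% intervals of the share of peaks on each chromosome, scaled to peaks per Mb. X is lowest in every list, at 4.29 per Mb for supported peaks against 11.8 on V and 25.6 on III.

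Peaks on X also scored lower and were narrower. A score of 3100 or more was reached by 10 of 76 supported X peaks (13.2%, 6.49 to 22.9) and by 570 of 1551 autosomal peaks (36.8%, 34.4 to 39.2), an odds ratio of 0.26 (Fisher's exact test, p = 1.19e-05). The corresponding odds ratios were 0.20 in replicate 1 (Fisher's exact p = 8.41e-07) and 0.10 in replicate 2 (p = 3.67e-08). The median width was 1263 bp on X and 1705 bp on the autosomes (two-sided permutation test of the difference, X minus autosomes, of -442 bp, p = 2e-05, the smallest it can give). The X peak with the highest score spanned 2089130 to 2090825 and scored 3165.68 in the combined list, 2942.7 in replicate 1 and 2982.64 in replicate 2. The X peak at 3073204 to 3077853 was 4650 bp wide and scored 3100 in the combined list, and that at 9604812 to 9608057 scored 3100 in all 3 lists.

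Along the autosomes, supported peaks were not concentrated in the chromosome centres. The central 50% of autosome length held 764 of 1551 peaks (49.3%, 46.7 to 51.8, exact binomial test, p = 0.576). Chromosome V alone passed the test, with 59.8% of its 246 peaks in the central part (53.3 to 65.9, adjusted p = 0.0159, exact binomial test). The remaining peaks were unevenly divided between the chromosome arms in 3 cases. On chromosome III, 55 peaks lay in the first 25% of the length and 115 in the last 25% (adjusted p = 2.92e-05, exact binomial test). On chromosome II these were 60 and 103 (0.00189), and on chromosome IV they were 103 and 60 (0.00189). On I, V and X the difference between the ends did not pass the test (0.348, 0.105 and 0.173). Among all combined-list peaks, the central 50% held 46.7% and passed the exact binomial test (p = 0.00508). Among the upper 50% of supported peaks by score it held 53.7%, on the other side of the expected share (exact binomial p = 0.0389). These tests count each peak as independent although peaks were clustered, so a value this near the threshold is weak.

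**Figure D4:**
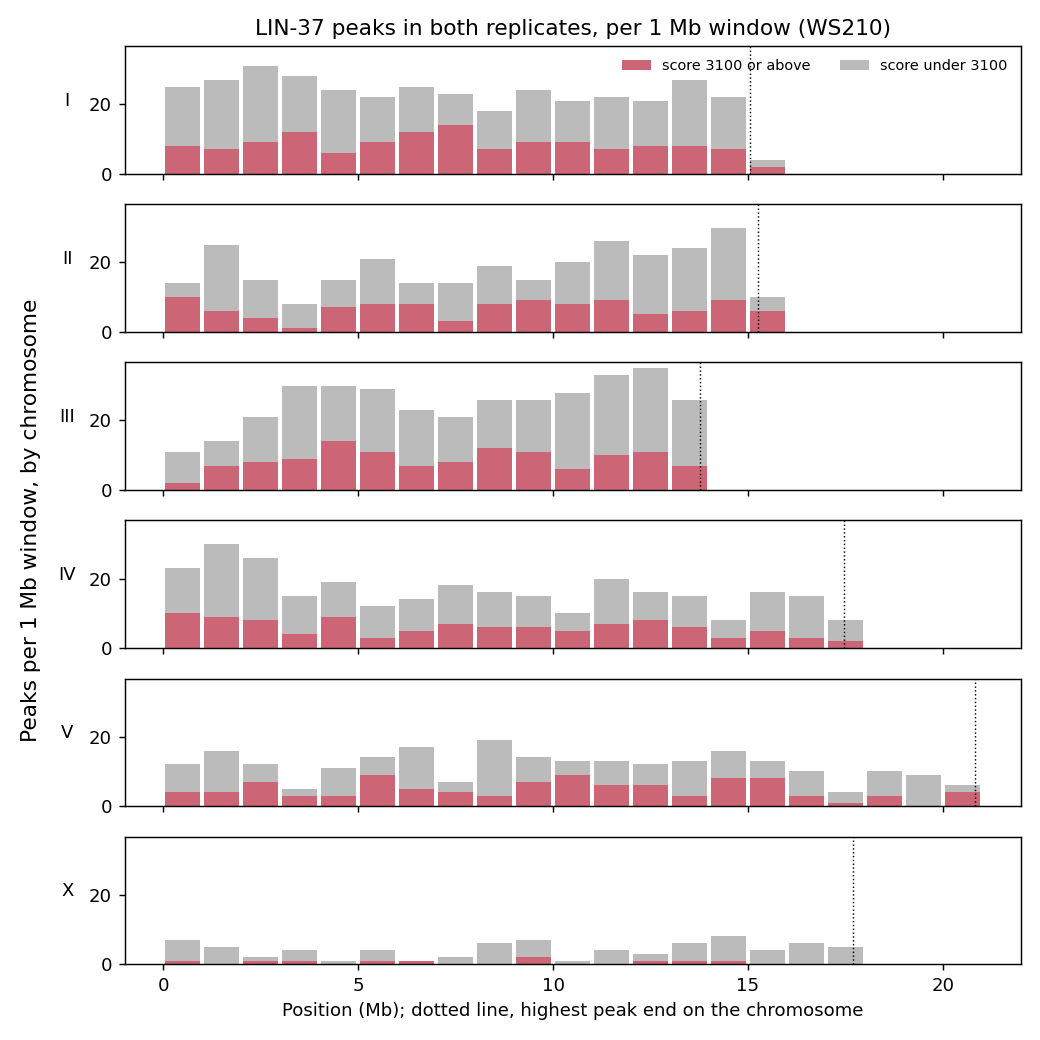
Supported peaks per 1 Mb window (y axis) along each chromosome (x axis, Mb, WS210), split into peaks scoring 3100 or above and peaks below. The fullest window of chromosome III, at 12 to 13 Mb, holds 35 peaks, and the fullest window of X, at 14 to 15 Mb, holds 8.

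Supported peaks were clustered on the scale of 100 kb. The 1003 windows held 1.62 ± 1.61 peaks (mean and SD across windows), and 295 held none. The variance to mean ratio was 1.59, against a mean of 1.32 and a maximum of 1.52 in random placements that kept the number per chromosome (one-sided permutation test, p = 1e-05, the smallest it can give). Placement within 2 Mb segments, which keeps broader differences in density, gave a mean of 1.37 (permutation p = 2e-05). The fullest window, at 8800001 to 8900000 on chromosome V, held 11 peaks between 8825016 and 8898917, none of which scored 3100 or more. The window at 2000001 to 2100000 on chromosome I held 10 peaks and that at 13800001 to 13900000 on chromosome II held 9, with 1 and 0 peaks at that score. These windows were chosen after their values were seen. A fullest window of 11 or more peaks had a permutation p of 0.0163 in random placements over the chromosome and of 0.0281 within 2 Mb segments. Neither placement keeps the uneven spread of genes, open chromatin or mappable sequence, so clustering beyond that spread was not tested.

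The peaks with the highest deposited combined-list scores were on several chromosomes. By the rule set in advance, the first 10 supported peaks by score were at 2915565 to 2916934 on IV (3228.29), 14990160 to 14991851 (3228.29), 20712284 to 20713779 (3227.04) and 9645074 to 9647217 (3218.01) on V, 2503816 to 2505388 (3226.07) and 592734 to 594088 (3182.65) on II, 8357454 to 8359024 on III (3219.64), 2829059 to 2831887 (3212.38) and 10172560 to 10174038 (3207.35) on I, and 2089130 to 2090825 on X (3165.68), with the authors' combined-list score in brackets. All 10 overlapped peaks of both replicates, as every supported peak does by definition. Their replicate 2 scores were between 1420.08 and 2982.64, all under 3100. Of their replicate 1 scores, 1 was 3225.28 (the peak at 9645074 on V) and the others were between 1800.99 and 2942.7. In the combined list 564 peaks were tied at exactly 3100 and 16 lay above it, so the score does not order these peaks. The 564 had median scores of 3100 in both replicates, while the 16 had medians of 2444 in replicate 1 and 2116 in replicate 2. The 10 peaks are therefore first by the deposited score only and are not shown to be the strongest.

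The widest supported region lay at 2418517 to 2427418 on chromosome V. It was 8902 bp wide and scored 3100 in all 3 lists, as 1 peak in replicate 1 and 2 in replicate 2. The next widest, at 5585967 to 5592895 on chromosome III, was 6929 bp wide and scored 3014.75 in the combined list, while its highest peak scored 3100 in each replicate. The region at 15076179 to 15082739 on chromosome IV was 6561 bp wide and was a single peak scoring 3100 in each list. In all, 24 supported peaks were wider than 5000 bp, of which 21 scored 3100 or more and none lay on X. These regions were chosen for their width after the values were seen.

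The first bases of all 6 chromosomes carried a peak in the combined list and in replicate 2, and in no case in replicate 1. These peaks lacked a start coordinate and were taken to begin at position 1. In replicate 2 these peaks ended between position 628 (IV) and 1574 (I), with scores from 257.9 (III) to 1649.72 (X). In the combined list they scored from 90.91 (III) to 335.25 (X). The first replicate 1 peak on each chromosome began between position 7550 (V) and 199872 (IV).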

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

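Alternatives added after seeing the data were the peaks without a start left out, the replicates' own lists, autosomes I to IV, the central 33.3%, other windows, all clustering and score-ceiling results, and the use of length in place of genes for the central share. No paired analysis was possible because the ChIP and input groups that share replicate numbers were not compared: peak lists were analysed for ChIP libraries only. Of the 28 alternatives, 20 kept the direction and the side of the threshold or stayed within the interval. The replicate overlap over random was 13.9 and ranged up to 48.0 (50% of both lengths). The overlap itself then fell from 80.1% to 63.4% of replicate 1 peaks. The limit of 50% of both lengths depends on width as well as position, and replicate 1 peaks were the narrowest. The X to autosome ratio (0.23) ranged from 0.15 (upper 50% by score) to 0.28 (replicate 1's own list), past the threshold each time. The share of combined-list peaks in both replicates (84.2%) moved to 60.7% with 50% of both lengths shared and to 100% (966 of 966) in the upper 50% by score. With support asked of 1 replicate only, it was 89.8% (replicate 2) to 92.2% (replicate 1). The rank correlation of scores (0.93) moved to 0.94 with 50% of both lengths shared and to 0.86 in the upper 50% of both lists; the smaller range of scores is part of that construction. The central share of the autosomes (49.3%, exact binomial p = 0.576) passed the threshold at 46.7% with all combined-list peaks and reversed to 53.7% in the upper 50% by score; the cause was not tested. Alternatives for promoters, divergent starts, gene lists and motifs were not run, nor were those for distances to gene starts. Read depth is unknown, so it cannot be said which missing peaks depth limits.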

Other observations

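The tests of the score of 3100 and of the chromosome beginnings were set before they were run, but after the patterns had been seen. For the beginnings, it was already known that all 6 were missed. The tests given here on X, on the chromosome centres and on dense windows were chosen after the values had been seen. A hypothesis drawn from the central shares under different peak sets, and examined on the same peaks, is that stronger and repeated peaks may lie more often in autosome centres. The central 50% of autosome length held 424 of 789 supported peaks in the upper 50% by score (53.7%, 50.2 to 57.3) and 340 of 762 in the lower 50% (44.6%, 41.1 to 48.2), an odds ratio of 1.44 (Fisher's exact test, adjusted p = 6.24e-04 over 5 tests). It held 93 of the 284 autosomal peaks that were not in both replicates (32.7%, 27.3 to 38.5) against 49.3% of the supported ones (Fisher's exact test, adjusted p = 1.40e-06). Without chromosome V, the odds ratios were 1.45 (Fisher's exact test, p = 0.000875) and 2.00 (Fisher's exact p = 4.61e-06). The direction of both contrasts follows from the shares that prompted the hypothesis. The tests therefore give the size of the differences and are not separate support for it. The contrasts are also not separate from each other, since support rose with score. Of the combined-list peaks, 21.1% of those under 100 and all of those at 500 or more were supported. Supported and other peaks of like score were not compared. The 156 peaks in the 22 windows of 100 kb with 6 or more supported peaks had a median score of 631.6, and 24.4% of them reached 3100, against a median of 1205 and 33.5% for the 248 peaks alone in their window (odds ratio 0.64, Fisher's exact test, adjusted p = 0.0581); the difference did not pass the threshold, and it depends on the limit of 6, since in windows of exactly 6 peaks 24 of 66 (36.4%) reached 3100.

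The lower share of X peaks at a score of 3100 or more, given in the report, can be put as densities from the same counts. The density on X relative to the autosomes was 0.31 (95% interval 0.24 to 0.40) for supported peaks under 3100 and 0.08 (0.04 to 0.15) for those at or above it. In the replicate lists, peaks without a partner lay on X more often than shared ones: 10.9% against 4.38% in replicate 1 (odds ratio 2.67, Fisher's exact test, adjusted p = 2.92e-06) and 10.3% against 4.58% in replicate 2 (odds ratio 2.40, Fisher's exact test, adjusted p = 0.00219). Peaks without a partner also scored lower (medians 80.5 and 80.3, against 841.8 and 745.3 for shared peaks). X had the lowest median score of all chromosomes in both replicate lists (221.6 and 276.1). Peaks of like score were not compared, so score and chromosome cannot be told apart here. The contrast between peaks with and without a partner was smaller in the combined list, where it was not tested. There 7.79% of peaks in replicate 1 only, 6.48% in replicate 2 only and 4.65% in neither lay on X, against 4.67% in both. All these shares were under the 17.7% of length that X makes up. A lower ChIP signal over the whole of X, and fewer or weaker LIN-37 sites there, were not tested, since neither read coverage nor gene positions were used, and both stay open.

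Scores of exactly 3100 may stand for p-values too small to represent, which would put them above the scores that exceed 3100. Of the 564 combined-list peaks at exactly 3100, 393 (69.7%) had a partner at exactly 3100 in both replicates, against 0 of the 16 peaks above 3100 (Fisher's exact test, p = 8.68e-09). The median replicate 1 score was 2444 for the peaks above 3100, 2172 for the 54 peaks from 2500 to under 3100, and 3100 for those at exactly 3100. Peaks above 3100 were also narrower than those at 3100 (median 1632 against 2210 bp, two-sided permutation test, p = 0.00046), but they were also narrower than the peaks from 2500 to under 3100 (1985 bp). If the scores of exactly 3100 are the highest, the 10 peaks named by score in the report are not the strongest in the list.

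The peaks at the beginnings of all 6 chromosomes in replicate 2 had no partner in replicate 1. A general failure of replicate 1 to find peaks of this score is argued against by the other peaks. Of the 528 other replicate 2 peaks scoring between 257.9 and 1649.72, replicate 1 missed 21 (3.98%, 2.48 to 6.02). At that share the chance of missing all 6 is 3.96e-09 if they were independent. That all 6 were missed was known when the test was set, so this chance is not separate evidence. A difference between the libraries in reads from the repeats at chromosome ends, and a limit on peaks at a chromosome's edge in the processing of replicate 1, were not tested and stay open.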
